A study of Tetranychus urticae with 23 samples.

How the data were processed

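Gene expression in adult females of the spider mite Tetranychus urticae was measured on 23 two-colour Agilent arrays. Per the labels, each array held Cy5-labelled RNA of one group and Cy3-labelled RNA of the London strain kept on bean. The groups were the strains MR-VP (6 arrays) and MAR-AB (5 arrays) kept on bean, and London mites kept on tomato for 2 h, for 12 h or for 5 generations (4 arrays each). Per the labels' protocols, mites were grown at 26 degrees C under 16 h of light and 8 h of dark, RNA came from about 100 females, and 100 ng was labelled. London was in Cy3 on all 23 arrays, so there were 0 dye swaps. The arrays lay on 5 slides. MR-VP used slides 1 and 2 with 3 arrays each, Tomato-2h and Tomato-12h shared slide 3, Tomato-5G was on slide 4 and MAR-AB on slide 5. Scan and slide gave the same batches, so scan was not tried apart from slide. MAR-AB and Tomato-5G each filled a slide of their own, so slide and group cannot be told apart for them.

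Per the file headers, images were read with Agilent Feature Extraction 10.5.1.1 (10.5 per the submitters' processing notes). The deposited scanner files held, for each spot and dye, the median pixel intensity of the spot and of its local background, and a processed intensity that was background-subtracted, spatially detrended and dye-normalized. They also held a log10 ratio, per the file headers, of processed red over processed green. It equalled that ratio, recomputed from the processed intensities, in 84.1% of the values, and was not used further. Mean pixel intensities, planned as the starting values, were not in the files, and median intensities took their place. The authors also deposited 1 list of genes per group with a signed fold change against London. How those genes were chosen is not stated in the files, and the lists hold no p-values.

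Median intensities were corrected with normexp (offset 50) and each array was normalized by loess, with control spots at weight 0. Each array held 62852 spots, of which 61533 were not controls. Spots flagged as outliers by the scanner software were left out, and no spot was saturated. Spots of 1 probe were averaged. A probe was kept where it was well above background in either dye on at least 4 arrays, which kept 45509 of 58985 probes. A target's value was the mean log2(Cy5/Cy3) of its kept probes, usually 3. Positive values mean more signal in the group than in London, read here as more RNA. For MR-VP and MAR-AB this reading takes the probes to match these strains as well as London, which was not checked.

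The array names 388 curated targets by gene (enzyme and transporter families and a few others) and carries 19213 unnamed targets known by an ID alone. Another 182 targets printed as repeated spots, 15 per probe, served only to measure spot noise. Tests covered 16008 targets, 374 of them curated and 15634 unnamed. The IDs of the curated targets, of the unnamed targets and of the authors' lists follow different numberings: the 266 IDs that occur as both a curated and an unnamed target correlated at only 0.0946 to 0.18 over the groups' means. The kinds of ID were therefore never joined. Of 110 curated targets called in a comparison, 69 had an unnamed target at a correlation over 0.98, against 21 of 110 unnamed targets drawn for comparison. Many curated genes are therefore probably also present under an unnamed ID. Counts for a comparison use the 15634 unnamed targets, and families and named genes use the curated ones. This choice was made after counts over all targets had been seen. None of the array's IDs, 0 in all, was found among the reference gene symbols, so unnamed targets keep their IDs and no genome position is given. Near-identical family members could share signal on a probe, which could not be checked without sequences of the genes.

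Tests used limma 3.58.1 in R 4.3.3 (files were read with data.table, version 1.17.8), with 1 mean per group over all 23 arrays and moderated statistics. London is the control RNA and has no arrays of its own, so each group's mean log2 ratio was tested against 0. This leaves out London's own spread, and a probe's dye bias stays in every such ratio. Contrasts between groups cancel the dye bias and any London RNA level common to all slides, but not differences of London between slides. A target was called where the Benjamini-Hochberg adjusted p over all 16008 targets was under 0.05 and the absolute mean log2 ratio was at least 1. Errors are SDs over a group's arrays. Simulated data held 16008 targets and independent noise sized from the median-centred arrays, with no dye, slide or pairing term. For each group against London, all 50 changed targets of each size were recovered at true log2 ratios of 1.5, 2, 3 and 4. The exception was 49 of 50 at a ratio of 2 in Tomato-12h. False calls numbered 0.

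Gene families were tested with camera (preset correlation 0.01), adjusted over all lists and groups, and again with an estimated correlation and with fry. Families were to be found by words in gene descriptions. The files hold no descriptions, so membership was taken from the names on the array: cytochrome P450s (103 tested), glutathione S-transferases (31), carboxyl/cholinesterases (85), ABC transporters (115), pesticide target sites (4) and the mitochondrial respiratory chain (4). The target site TuCCE-41-AChE also counts among the carboxyl/cholinesterases. Marker lists were ecdysteroid synthesis (5, neverland and P450s that also count in the P450 list) and nervous system (5, names ending in -nrl or -nrt). That adaptation was made after the files had been read, and 2 targets with truncated chitin names and some nervous system names were dropped after first medians had been seen. No member of either list was called. Planned lists for UDP-glycosyltransferases, intradiol dioxygenases, lipocalins, proteases, transporters of other kinds, heat shock and ribosomal proteins, and other tissues could not be formed and were not analysed here. Counts of called family members adjusted over the list alone were the same as those over all targets.

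Named genes followed a rule written before the data were examined. Per group it takes the 5 highest and 5 lowest called targets with one sign on every array, up to 2 called members per family and direction, and all pesticide target sites. Per contrast it takes the 3 highest and 3 lowest, and for Tomato-5G with both strains the 5 shared targets of largest size. Most of the highest and lowest targets are unnamed, and IDs are printed for only 4 of them. A target not well above background on any array of one side is given as a bound, from channel values after loess and Aquantile normalization, which stays open to dye bias.

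Correlations and overlaps between groups share London and the dye. They were set against 50 simulated draws of unchanged groups with a shared term of SD 0.222, taken from the Tomato-2h ratios, and against the overlap of independent lists. London could not be split. Alternatives covered background correction, the offset, processed intensities (centred on the median, with no loess), median centring in place of loess, the filter, the brightest probe, flagged spots, the arrays in the fit, array weights, the fold limit, the slide, the replicate number, subtraction of Tomato-2h, leaving out each array, and the authors' lists. Whether replicate numbers pair the arrays was checked by correlating deviations from group means. They paired Tomato-2h with Tomato-12h, at 0.167 to 0.696 in all 4 pairs, each array correlating best with its own number. The labels do not say what a number shares. No other pair of groups passed this check.

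The share of spots well above background in either dye was 63.7% to 76.1% per array, outlier flags took 0.133% to 0.327% of spots, and the SD between repeated spots was 0.0808 to 0.142. The number of arrays per group limits the precision. All 23 arrays were used.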

Results

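Transcript levels were compared on 23 arrays between adult female spider mites of 5 groups and the London strain kept on bean. MR-VP (6 arrays) and MAR-AB (5 arrays) are other strains kept on bean, known as resistant to several pesticides, which the labels do not state. In 3 further groups of 4 arrays each, London mites had spent 2 h, 12 h or 5 generations on tomato (Tomato-2h, Tomato-12h and Tomato-5G). The title of the series concerns a link between a change of host plant and pesticide resistance. The comparisons therefore address what differs in the strains, what changes on tomato, and whether the changes overlap. Values are mean log2 ratios of a group over London with the SD over its arrays, and a target was called where limma's adjusted p was under 0.05 and the size at least 1. The naming rule took only called family members with one sign on every array of the group.

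In MR-VP, among cytochrome P450s, enzymes that oxidize plant compounds and pesticides, 25 of 103 rose and 0 fell. CYP392D2 rose by 4.80 ± 0.92 (SD, n = 6), adjusted p = 6.88e-15, and CYP392D10p by 4.56 ± 0.40, adjusted p = 1.03e-19. Of 31 glutathione S-transferases, which conjugate compounds to glutathione, 5 rose and 0 fell, led by TuGSTm09 at 2.60 ± 0.64 and TuGSTm07 at 2.14 ± 0.85. Carboxyl/cholinesterases, a family of ester-cleaving enzymes, moved both ways, with 3 of 85 higher and 6 lower. TuCCE-49 rose by 2.56 ± 0.40 and TuCCE-56 by 1.36 ± 0.27, whereas TuCCE-51 fell by 3.63 ± 1.20 and TuCCE-03 fell by 1.38 ± 0.24. Of 115 ABC transporters, which export compounds across membranes, 0 rose and 1 fell, TuABCG-12, by 1.44 ± 0.45; its 2 probes stood at -2.84 and -0.03. With the brightest probe alone TuCCE-03 and TuABCG-12 were not called. From the scanner's processed intensities, which here and below were centred on the median with no loess, 5 ABC transporters were higher and 3 lower, and 9 carboxyl/cholinesterases were higher and 10 lower. Under median centring in place of loess 8 glutathione S-transferases were higher.

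As a list, P450s were shifted upward in MR-VP (camera adjusted p = 0.00183) and carboxyl/cholinesterases downward (adjusted p = 0.0264). The mean of the P450s was 0.536 but their median 0.0848, and 78 of 103 were not called, so most of the list moved little. With an estimated correlation between genes, the adjusted p was 0.776 for both lists. After median centring in place of loess, the called carboxyl/cholinesterases turned to 7 higher and 3 lower, and the list's adjusted p to 0.081. Glutathione S-transferases (adjusted p = 0.18, but 0.0145 under median centring) and ABC transporters (adjusted p = 0.892) did not pass. Among the 15634 unnamed targets, 605 were called, 268 higher and 337 lower. The 5 highest of all targets ranged up to 5.91 and included CYP392D2. Tetur28g01310 rose by 5.23 ± 0.96, with London well above background on 3 of 6 arrays, and Tetur32g00960 fell by 7.59 ± 0.45. Called targets numbered 1059 with no normexp offset and 1755 from processed intensities, and the share called higher moved from 44.3% to 64% under median centring. Within the group the arrays of slide 1 alone gave 752 called targets, those of slide 2 alone 596, and slide as a block 606.

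In MAR-AB, P450s rose in 31 of 103 cases and fell in 1. CYP392A11, an enzyme known to hydroxylate the acaricides cyenopyrafen and fenpyroximate, rose by 6.88 ± 0.13 (SD, n = 5), adjusted p = 3.24e-23, and CYP392A12 by 5.67 ± 0.13, adjusted p = 3.26e-22. CYP392E7 fell by 1.50 ± 0.20 as a mean of probes that ranged from -4.14 to 0.56. Of 31 glutathione S-transferases, 8 rose and 1 fell: TuGSTd14 rose by 3.50 ± 0.33 and TuGSTd09 by 2.30 ± 0.38, and TuGSTd08 fell by 1.66 ± 0.26. Of 85 carboxyl/cholinesterases, 8 rose, among them CCEinc-07 at 2.86 ± 0.29 and TuCCE-33 at 2.04 ± 0.27. In the same family 5 fell, among them CCEinc-09 at -2.59 ± 0.42 and CCEinc-18 at -1.32 ± 0.29; the family's counts became 20 higher and 1 lower under median centring and 17 and 7 from processed intensities. Of 115 ABC transporters, 4 rose, including TuABCC-02 at 1.20 ± 0.17 and TuABCC-07 at 1.17 ± 0.14, and TuABCG-12 fell by 1.18 ± 0.08. Its 2 probes stood at -2.10 and -0.25. From processed intensities 18 ABC transporters were higher and 2 lower, and under median centring 11 and 0, with 16 glutathione S-transferases higher. CYP392E7, CCEinc-18 and TuABCG-12 were not called under median centring or with the brightest probe alone, and TuABCC-02 was not after subtraction of Tomato-2h.

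The P450 list (camera adjusted p = 1.05e-10) and the glutathione S-transferase list (adjusted p = 0.000799) were shifted upward in MAR-AB. With an estimated correlation their adjusted p was 0.244 and 0.776. Carboxyl/cholinesterases (adjusted p = 0.59) and ABC transporters (adjusted p = 0.251) did not pass. Among unnamed targets 675 were called, 325 higher and 350 lower. Tetur28g01310 rose by 5.90 ± 0.24, with London above background on 2 of 5 arrays. Tetur43g00090 was not well above background on any MAR-AB array and was at least 442-fold lower, adjusted p = 7.02e-18. Called targets numbered 1356 with no offset, 2319 from processed intensities and 1212 under median centring. The share called higher was 48.1% in the main setting, 63.3% from processed intensities and 75.7% under median centring. Slide and group cannot be told apart for MAR-AB.

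**Figure D1:**
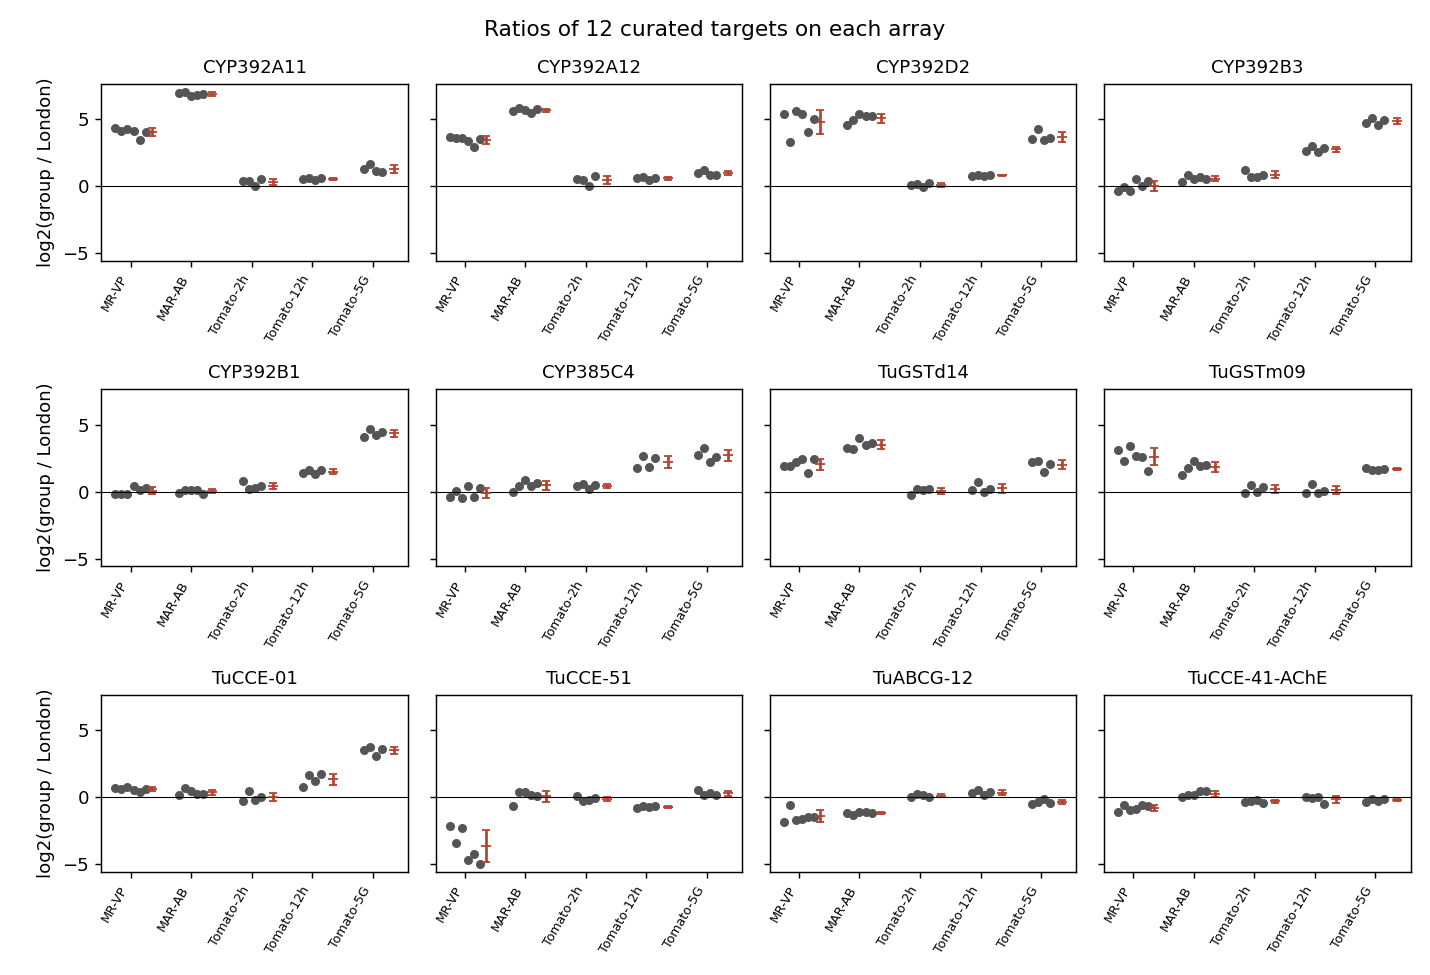
Log2 ratios over London (vertical axis) of 12 curated targets on each array, by group along the horizontal axis. Grey points are arrays and the red mark is the group's mean with its SD; CYP392A11 and CYP392A12 sit highest in MAR-AB, at 6.88 and 5.67, and CYP392B3 and CYP392B1 in Tomato-5G, at 4.85 and 4.36.

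The strains also differed from each other, in a contrast that cancels the dye and any London RNA level common to all slides, but not differences between slides. MR-VP was lower than MAR-AB in 14 P450s and higher in 3 of 103. CYP392A11 was lower in MR-VP by -2.83 (adjusted p = 2.09e-13) and CYP392A12 by -2.22 (adjusted p = 6.67e-12). TuCCE-51 differed by -3.71 (adjusted p = 6.1e-08), TuGSTd14 by -1.44 (adjusted p = 3.8e-06) and TuABCC-07 by -1.22 (adjusted p = 8.3e-07). Acetylcholinesterase (TuCCE-41-AChE), the target of organophosphates and carbamates, was lower in MR-VP by -1.03 (adjusted p = 2.91e-07). CCEinc-09 was higher in MR-VP by 1.43. Of glutathione S-transferases, 0 were higher and 4 lower, and of carboxyl/cholinesterases 1 was higher and 8 lower. Of 15634 unnamed targets 520 were called, 221 higher and 299 lower, with 1066 and no offset and 1732 from processed intensities. Of the 3 highest, 2 stood at 3.00 and 3.19, and the other, Tetur43g00090, was not well above background on any of 5 MAR-AB arrays. Of the 3 lowest, 1 stood at -4.18, and the other 2 were well above background on 0 and 3 of 6 MR-VP arrays.

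After 2 h on tomato few transcripts passed the threshold against London on bean. A single P450 was called, CYP389A1, which rose by 1.16 ± 0.34 (SD, n = 4), adjusted p = 1.75e-06; 10 P450s were higher under median centring and 4 from processed intensities. No glutathione S-transferase, carboxyl/cholinesterase or ABC transporter was called, the largest member values being 0.46, 0.59 and -0.75; from processed intensities 3 ABC transporters were higher. No list passed camera, with adjusted p = 0.251 for P450s, 0.186 for glutathione S-transferases, 0.714 for carboxyl/cholinesterases and 0.251 for ABC transporters. Under median centring the glutathione S-transferase list passed, with adjusted p = 0.00614. Of the unnamed targets 40 were called, 30 higher and 10 lower, and the 5 highest named by the rule spanned 1.36 to 1.86. Without Tomato-2h array 2 the calls were 27, 25 higher and 2 lower, and with slide as a random block 31, 26 higher and 5 lower. Called targets numbered 150 with no offset, 599 from processed intensities and 489 under median centring. The share called higher was 75% in the main setting, 90.3% from processed intensities and 97.1% under median centring. The authors' list for this group held 13 genes.

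After 12 h on tomato 12 of 103 P450s had risen and 0 had fallen, against 29 and 0 under median centring and 23 and 1 from processed intensities. CYP392B3 rose by 2.75 ± 0.21 (SD, n = 4), adjusted p = 5.56e-13, and CYP385C4 by 2.21 ± 0.47, adjusted p = 1.91e-09. Among carboxyl/cholinesterases TuCCE-01 rose by 1.33 ± 0.43 and TuCCE-36 by 1.18 ± 0.14, and the 2 that fell were TuCCE-12 at -1.27 ± 0.29 and TuCCE-23 at -1.02 ± 0.22, out of 5 higher and 2 lower of 85 (9 and 0 under median centring). TuABCC-10 at 1.12 ± 0.14 and TuABCG-09 at 1.07 ± 0.09 were the 2 ABC transporters that rose, and 0 fell, against 10 and 1 from processed intensities. TuCCE-12 and TuCCE-23 were not called under median centring, and neither they nor TuCCE-36 and TuABCG-09 were after subtraction of Tomato-2h. No glutathione S-transferase was called, against 2 higher under median centring and 1 from processed intensities. The P450 list was shifted upward (camera adjusted p = 1.28e-05; adjusted p = 0.716 with an estimated correlation), and glutathione S-transferases (adjusted p = 0.941), carboxyl/cholinesterases (0.749) and ABC transporters (0.893) did not pass. Of unnamed targets 333 were called, 191 higher and 142 lower. Tetur46g00020 rose by 4.03 ± 0.65, and the 5 lowest spanned -4.64 to -3.12. Called targets numbered 574 with no offset, 1153 from processed intensities, 565 under median centring and 150 after subtraction of Tomato-2h. The share called higher moved from 57.4% to 75% from processed intensities and 86.4% under median centring.

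After 5 generations on tomato, changes were larger and went both ways. P450s rose in 19 of 103 cases and fell in 5. CYP392B3 rose by 4.85 ± 0.23 (SD, n = 4), adjusted p = 9.85e-19, and CYP392B1 by 4.36 ± 0.26, adjusted p = 2.43e-19, while CYP392A9v2 fell by 1.83 ± 0.17 and CYP392A8 fell by 1.32 ± 0.17. Of 31 glutathione S-transferases 5 rose, including TuGSTd15 at 2.16 ± 0.65 and TuGSTd14 at 2.02 ± 0.35, and TuGSTd05 fell by 1.09 ± 0.07. Of 85 carboxyl/cholinesterases 11 rose, led by TuCCE-01 at 3.50 ± 0.28 and TuCCE-49 at 2.45 ± 0.29. Another 6 fell, among them CCEinc-13 at -1.86 ± 0.48 and CCEinc-04, with 1 probe, at -1.78 ± 0.13. The family's counts became 14 higher and 10 lower from processed intensities and 15 and 4 under median centring. Of 115 ABC transporters TuABCC-11 rose by 1.09 ± 0.17 and pABC-26 by 1.05 ± 0.11 among 3 higher, whereas the 2 lower were pABC-03 at -1.25 ± 0.07 and ABCCinc-04 at -1.03 ± 0.32; with no offset these counts became 4 higher and 7 lower, from processed intensities 10 and 5, and under median centring 4 and 0. TuGSTd05, pABC-03 and ABCCinc-04 were not called under median centring, and TuGSTd05 and pABC-26 were not after subtraction of Tomato-2h. Glutathione S-transferases were 8 higher and 1 lower from processed intensities.

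As lists in Tomato-5G, P450s were shifted upward (camera adjusted p = 0.0195; adjusted p = 0.776 with an estimated correlation). Glutathione S-transferases (adjusted p = 0.18, but 0.0145 under median centring), carboxyl/cholinesterases (0.941) and ABC transporters (0.251) did not pass. Carboxyl/cholinesterases had a median of -0.05 and a mean of 0.09, with the test pointing down. Of unnamed targets 936 were called, 397 higher and 539 lower. Tetur46g00020 rose by 9.05 ± 0.29 and Tetur28g01310 by 8.26 ± 0.17. Tetur32g00960 fell by 8.60 ± 0.47, and Tetur43g00090, above background on 1 of 4 group arrays, fell by 8.61 ± 0.18. Called targets numbered 1462 with no offset and 2377 from processed intensities, and 42.4% of calls were higher in the main setting, 56.9% from processed intensities and 58.1% under median centring. Slide and group cannot be told apart for Tomato-5G.

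**Figure D2:**
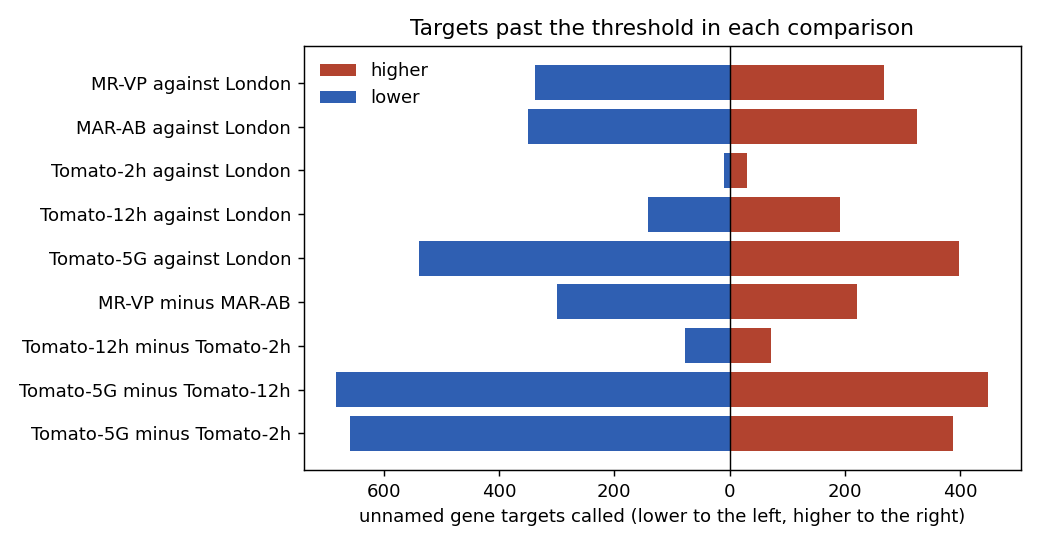
Number of unnamed targets called higher (to the right, red) and lower (to the left, blue) in each comparison, in targets. Tomato-2h gave 40 and Tomato-5G 936 against London, and Tomato-5G minus Tomato-12h gave 1130.

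The tomato groups were compared with each other, which cancels the dye and any London RNA level common to the slides. Between 2 h and 12 h, arrays of 1 slide, 9 P450s rose and 0 fell: CYP392B3 rose by 1.88 (adjusted p = 3.02e-07) and CYP385C4 by 1.79 (adjusted p = 4.76e-05). TuCCE-01 rose by 1.33 and TuABCC-10 by 1.24. Of unnamed targets 150 were called, 72 higher and 78 lower, with 281 from processed intensities. From 12 h to 5 generations 10 P450s rose and 7 fell. CYP392B1 rose by a further 2.86 (adjusted p = 8.25e-13) and TuCCE-01 by 2.17, whereas CYP392A9v2 differed by -1.95 and TuABCG-09 by -1.28. Glutathione S-transferases rose in 6 cases and fell in 1, TuGSTd15 by 2.02 and TuGSTd14 by 1.77. Tomato-5G lay on another slide than the earlier times, so slide and group cannot be told apart in this step. Here 1130 unnamed targets were called, 448 higher and 682 lower (1842 with no offset, 2791 from processed intensities). Against 2 h the count was 1046, 388 higher and 658 lower (1742 and 2664), with 15 P450s higher and 6 lower and 5 glutathione S-transferases higher and 0 lower. Tetur46g00020 was the highest target, at 8.33. Tetur43g00090 was among the 3 lowest, with 1 of 4 Tomato-5G arrays well above background.

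Pesticide target sites were measured as 4 genes and none was called in a group in the main setting. In MR-VP acetylcholinesterase was called lower from processed intensities and with no offset. Acetylcholinesterase stood at -0.79 ± 0.22 in MR-VP and 0.24 ± 0.22 in MAR-AB, and at -0.31 ± 0.12, -0.14 ± 0.25 and -0.21 ± 0.10 in Tomato-2h, Tomato-12h and Tomato-5G. The voltage-gated sodium channel (VGSC), the pyrethroid target, stood at 0.28 ± 0.19 in MR-VP, 0.13 ± 0.16 in MAR-AB, and between -0.17 and 0.05 on tomato. The GABA receptor gene GABA2 ranged from -0.02 in MAR-AB to 0.15 in MR-VP. Acetyl-CoA carboxylase (ACCase), the target of ketoenol acaricides, ranged from -0.57 in Tomato-12h to -0.12 in MR-VP. For the target sites in MR-VP the median was positive, at 0.0167, and the mean negative, at -0.12. Adjusted camera p values of the target site list were 0.892 in MR-VP, MAR-AB and Tomato-5G, 0.18 in Tomato-2h and 0.251 in Tomato-12h. Members of the respiratory chain (medians -0.0655 to 0.186), of ecdysteroid synthesis (-0.393 to 0.217) and of the nervous system markers (-0.326 to 0.101) were not called in a group, and their smallest adjusted camera p was 0.18. With median centring the respiratory chain list passed in MR-VP (adjusted p = 0.0186) and, with its direction turned upward, in Tomato-2h (adjusted p = 0.0379).

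Genes changed after 5 generations on tomato overlapped with those changed in the strains. In Tomato-5G and both strains 218 unnamed targets were called one way, 78 higher and 140 lower, where independent lists would share 0.141 and 0.26. Tetur28g01310 was among them, at 5.23, 5.90 and 8.26 in MR-VP, MAR-AB and Tomato-5G, and Tetur32g00960 at -7.59, -4.86 and -8.60. In MAR-AB the 3 probes of Tetur32g00960 ranged from -7.5 to -1.2. For Tetur28g01310 London was well above background on only 3 of 6 MR-VP arrays and 2 of 5 MAR-AB arrays. Of curated targets 16 were higher and 1 lower in all 3, and the following were chosen after their values were seen. CYP392D2 stood at 4.80, 5.06 and 3.70 in MR-VP, MAR-AB and Tomato-5G, CYP392D7 at 3.53, 4.70 and 2.81, TuGSTd14 at 2.06, 3.50 and 2.02, and TuCCE-49 at 2.56, 1.83 and 2.45. The 1 lower was CCEinc-13, at -1.15, -1.28 and -1.86, with probes in Tomato-5G from -3.33 to -0.86.

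Tomato-5G and MR-VP shared 332 targets called the same way and 21 the opposite way: 126 were higher in both against 6.81 for independent lists, and 206 lower against 11.6. Tomato-5G and MAR-AB shared 324 and 24, with 127 higher against 8.25 and 197 lower against 12.1. MR-VP and MAR-AB shared 318 and 6, with 139 higher against 5.57 and 179 lower against 7.54. Across the 15634 targets, which are not independent, r was 0.531, 0.465 and 0.607 in the same order, and rho 0.47, 0.41 and 0.399. In simulation, groups with no effect shared a London and dye term sized from all Tomato-2h spread beyond noise. They gave r of 0.863, 0.853 and 0.877, above the observed r. Their covariance was 0.0491, 0.0491 and 0.049, against 0.155, 0.149 and 0.135 observed. Measured Tomato-2h ratios covaried with MR-VP, MAR-AB and Tomato-5G at only 0.0116, 0.00751 and 0.00915. The simulated term was therefore too large, so its r and covariance do not measure what London and the dye share. At most 0.22 simulated targets were called in both, but a term of SD 0.222 seldom reaches the limit of 1. Part of the overlap may still come from the shared London RNA, which could not be split. Tomato-5G minus Tomato-2h, which cancels the dye and any London RNA level common to both slides, correlated with MR-VP at 0.469 and with MAR-AB at 0.421, and 311 and 324 targets were called the same way.

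**Figure D3:**
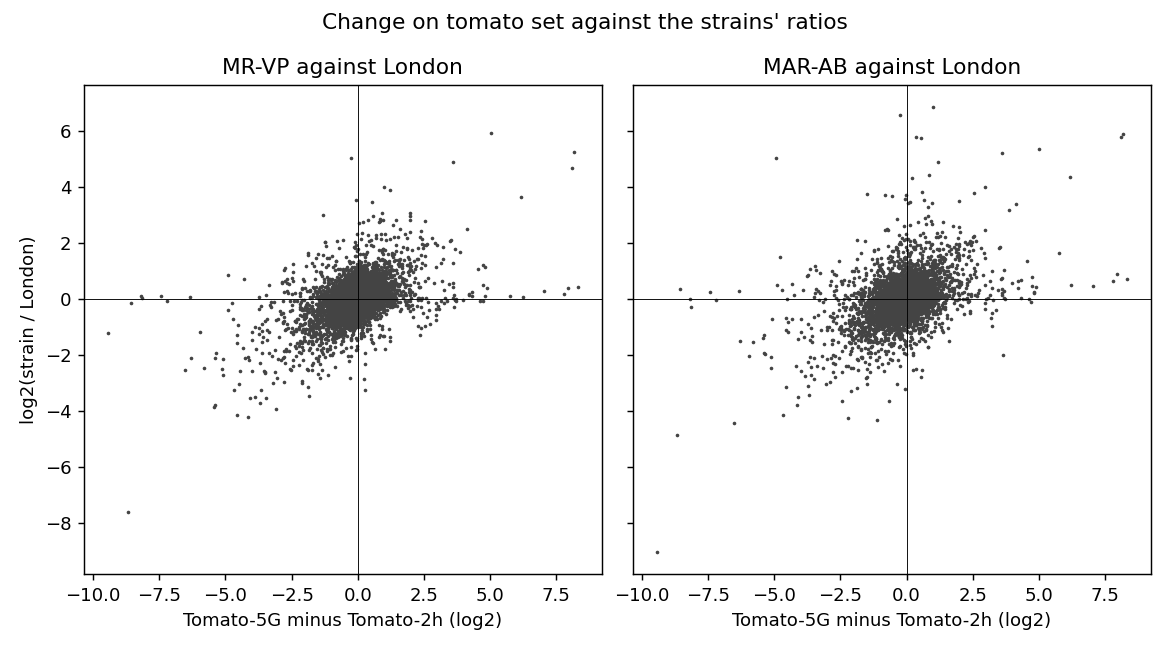
Log2 difference between Tomato-5G and Tomato-2h (horizontal axis) against the log2 ratio over London (vertical axis) of MR-VP (left) and MAR-AB (right). Each point is 1 of 15634 unnamed targets; r was 0.469 and 0.421.

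The lists the authors deposited held 893 genes for MR-VP (461 higher), 977 for MAR-AB (519 higher), 13 for Tomato-2h (10 higher), 416 for Tomato-12h (211 higher) and 1205 for Tomato-5G (571 higher). By their own IDs, Tomato-5G shared 463 genes with MR-VP, 442 of them in one direction, and 454 with MAR-AB, 413 of them in one direction. In all 3 lists 286 genes appeared, 272 in one direction. The shorter Tomato-12h list shared 73 genes with MR-VP, 44 of them in one direction, and 101 with MAR-AB, 71 of them in one direction. The smallest size in 4 of the 5 lists was a fold of 2, and the IDs could not be joined to the targets used here.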

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

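The correlation of Tomato-5G minus Tomato-2h with the strains was planned, but the limits it was read against were set after it had been seen. Tests chosen after the result they concern had been seen were the test of dye bias common to all slides, the test of a shift of the slide shared by Tomato-2h and Tomato-12h, and the test for a slide, scan or labelling batch in MR-VP. The requirement that a London-channel test hold with each array left out was also added after its first values were seen.

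Among 76 groups of values tested, 6 held an array far from its others, and chance alone gives about 1 in 20. TuABCG-12 stood at -0.58 on MR-VP array 2 and at -1.87 to -1.45 on the others. TuABCC-02 stood at 0.908 on MAR-AB array 1 against 1.23 to 1.34, and VGSC at 0.407 on MAR-AB array 4 against -0.0244 to 0.0959. CYP392A8 stood at -1.57 on Tomato-5G array 4 against -1.25 to -1.20, and TuGSTd05 at -0.99 on Tomato-5G array 3 against -1.14 to -1.11. On MAR-AB array 3, 69.4% of spots were well above background, against 73.2% to 74.5%.

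Differences between MR-VP and MAR-AB passed the test of the difference itself in 520 unnamed targets and in 11 of the curated genes that the rule named for either strain. Lower in MR-VP were TuCCE-51 (-3.71), CYP392A11 (-2.83), CYP392A12 (-2.22), CCEinc-07 (-1.92), TuCCE-33 (-1.59), TuGSTd14 (-1.44), TuABCC-07 (-1.22), TuGSTd09 (-1.21), TuCCE-03 (-1.06) and TuCCE-41-AChE (-1.03). CCEinc-09 was higher, at 1.43. Their adjusted p ranged from 2.09e-13 to 4.59e-05. Of all 45 curated genes named for any group, 12 passed.

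Between 2 h and 12 h on tomato the difference passed in 150 unnamed targets and, of the curated genes named for either time, in CYP392B3 (1.88), CYP385C4 (1.79), TuCCE-01 (1.33) and TuABCC-10 (1.24). Between 12 h and 5 generations it passed in 1130 unnamed targets. Of the genes named for either of these groups, those higher after 5 generations were CYP392B1 (2.86), TuCCE-01 (2.17), CYP392B3 (2.10), TuGSTd15 (2.02), TuCCE-49 (1.93), TuGSTd14 (1.77) and TuCCE-12 (1.52). Those lower were CYP392A9v2 (-1.95), CCEinc-04 (-1.76), CYP392A8 (-1.57), TuABCG-09 (-1.28), CCEinc-13 (-1.22) and pABC-03 (-1.13). The largest adjusted p among these genes was 0.000945. Of the 45 genes named for any group, 5 passed between 2 h and 12 h and 19 between 12 h and 5 generations.

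Other splits of the arrays were counted for each result. Swapping the sign of MR-VP arrays gave as many calls in 1 of 32 patterns, the real one, with 605 calls against at most 313 in another. That share is under 0.05 but is the smallest the swaps can give, so chance is not excluded outright. Sign swaps also cannot tell a probe's dye bias from a change in the group. The other groups have too few patterns to reach a share under 0.05: the real one was the 1 highest of 16 for MAR-AB (675 against at most 220) and of 8 for Tomato-2h (40 against 0), Tomato-12h (333 against 0) and Tomato-5G (936 against 0). For the contrasts, 1 of 100 splits drawn for MR-VP minus MAR-AB gave as many (520 against 335). The same held for 1 of 35 each in Tomato-5G minus Tomato-12h (1130 against 0) and Tomato-5G minus Tomato-2h (1046 against 0). These shares are under 0.05 but are the smallest the splits can give, so chance is not excluded outright. These splits take no account of slide: in all 3 contrasts the real split also parted the slides, so they do not exclude a difference between slides. For Tomato-12h minus Tomato-2h 1 of 35 splits gave as many (150 against 1), but replicate numbers pair these arrays. Among the 8 splits that part all 4 pairs the highest other gave 0, which is too few splits to reach a share under 0.05.

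The ratios of Tomato-5G resembled those of both strains. Dye bias and London RNA shared by all ratios are argued against as the whole source, since Tomato-5G minus Tomato-2h still correlated with each strain at 0.421 or more. London RNA of a different state on the Tomato-5G slide is argued against too, since over the 218 shared targets the London channel carried 1.64% of the median difference from the Tomato-2h slide (0.491% to 2.02% with each array left out). What stays open is the slide of Tomato-5G in its Cy5 channel, which cannot be told apart from the group. Also open is an untested biological explanation, that transcripts changed after 5 generations on tomato are also those that differ in the strains. Shorter stays on tomato resembled Tomato-5G less than the strains did. Across targets r of Tomato-5G was 0.169 with Tomato-12h and 0.0583 with Tomato-2h, against 0.531 with MR-VP and 0.465 with MAR-AB. By rho both shorter stays stood at 0.126, against 0.47 with MR-VP and 0.41 with MAR-AB. Tomato-2h arrays correlated with each other at only 0.492 to 0.71, and few targets were called, which by itself can lower the values for that group.

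The 40 targets called in Tomato-2h were small in size, with a median of 1.16. London RNA of that slide is argued against, since its channel carried 4.42% of the median ratio (1.03% to 8.39% with each array left out). Dye bias common to all slides would give these targets a like ratio in every group. In the groups on other slides they stood at up to 29.5% of that median (5.27% in MR-VP, 29.5% in MAR-AB and 22.6% in Tomato-5G). These values argue against it as the whole source of the 40 calls. The MAR-AB value lay between the limits set for and against it, so how large a part it has stays open. The 40 targets were also picked by their Tomato-2h ratios, which by itself can make their ratios smaller elsewhere. A shift of the whole slide stays open as well, since 30 of the 40 were called the same way in Tomato-12h, which shares that slide, and an early tomato response that lasts would look alike.

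The MR-VP arrays parted by slide, correlating at 0.732 to 0.935 within a slide and 0.632 to 0.765 between slides. Between the slides 220 targets were called, 142 higher on slide 1 and 78 lower, and 1 of the 10 splits of the 6 arrays gave as many, the highest other giving 7. Of the 220, 51 were among the targets called for MR-VP, and 5 P450s were higher on slide 1. The London channel carried 51.1% of the median difference (46.3% to 53.8% with each array left out), so London RNA differing between the slides stays open for part of it. A slide, scan or labelling batch and a difference between the mite samples cannot be told apart for the rest, since each slide held other samples.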

How the results depend on the processing

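All alternatives were fixed before the data were examined except the count over curated and unnamed targets together and the replicate block within Tomato-2h and Tomato-12h, which were chosen after seeing the data. Below, counts of called targets follow the order MR-VP, MAR-AB, Tomato-2h, Tomato-12h and Tomato-5G against London, then MR-VP minus MAR-AB, Tomato-12h minus Tomato-2h, Tomato-5G minus Tomato-12h and Tomato-5G minus Tomato-2h. The main counts were 605, 675, 40, 333, 936, 520, 150, 1130 and 1046. From processed intensities, centred on the median with no loess, they were 1755, 2319, 599, 1153, 2377, 1732, 281, 2791 and 2664. With normexp offset 0 they were 1059, 1356, 150, 574 and 1462 against London and 1066, 1842 and 1742 in the contrasts other than Tomato-12h minus Tomato-2h. Median centring gave 1212, 489 and 565 in MAR-AB, Tomato-2h and Tomato-12h. Of the main calls, 920 of 936 in Tomato-5G and 38 of 40 in Tomato-2h were also called from processed intensities. Adjusted p alone gave 8169, 7975, 4418, 5782, 8967, 6033, 660, 7734 and 7316, since the fold limit was dropped. Tomato-12h minus Tomato-2h in place of the ratio gave 150 for Tomato-12h, and the authors' list held 13 for Tomato-2h. The cause of these other differences was not tested. The other alternatives kept these counts within 1.5 times, among them slide as a random block (consensus correlation 0.218; 31 for Tomato-2h). Leaving out each array gave 27 to 54 for Tomato-2h, 315 to 362 for Tomato-12h, 926 to 960 for Tomato-5G, 576 to 655 for MR-VP and 664 to 693 for MAR-AB.

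The median of all unnamed targets differed between settings: it was 0.0146, 0.0117, 0.00805, 0.0152 and 0.0094 in the main setting, 0.101, 0.126, 0.108, 0.117 and 0.113 from processed intensities, and 0.158, 0.256, 0.179, 0.191 and 0.129 under median centring. Relative to that median, the P450 median in MAR-AB was 0.414, 0.567 and 0.562, and the carboxyl/cholinesterase median in MR-VP -0.177, -0.271 and -0.153. Family counts moved too, and the cause was not tested. From processed intensities carboxyl/cholinesterases were 9 higher and 10 lower in MR-VP, and ABC transporters 5 and 3 in MR-VP, 10 and 1 in Tomato-12h and 10 and 5 in Tomato-5G. Under median centring glutathione S-transferases were 8 higher and 0 lower in MR-VP, carboxyl/cholinesterases 9 and 0 in Tomato-12h, and ABC transporters 11 and 0 in MAR-AB.

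With the replicate block the contrasts gave 566, 160, 1133 and 1047, and 147 within the Tomato-2h and Tomato-12h arrays. For the 45 curated genes named by the rule the block changed no call in any contrast. Of all 374 curated targets, it added 3 calls in MR-VP minus MAR-AB and 1 in Tomato-5G minus Tomato-2h and lost 0. Apart from Tomato-2h with Tomato-12h, numbers did not pair the arrays. Against London it was not run, since each ratio already pairs the 2 dyes of an array, and scan was not run apart from slide.

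Targets called the same way numbered 934, 1031 and 923 from processed intensities for Tomato-5G with MR-VP, Tomato-5G with MAR-AB and MR-VP with MAR-AB, and r of Tomato-5G with MAR-AB was 0.498. With Tomato-2h subtracted from Tomato-5G, r was 0.469 with MR-VP and 0.421 with MAR-AB, and 0.511 for MR-VP with MAR-AB minus Tomato-2h.

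With an estimated correlation no list passed: adjusted p was 0.776 for P450s in MR-VP and Tomato-5G, carboxyl/cholinesterases in MR-VP and glutathione S-transferases in MAR-AB, 0.244 for P450s in MAR-AB and 0.716 in Tomato-12h. fry, which does not compare a list with other genes, passed more lists. Its adjusted p in MR-VP was 0.00147 for glutathione S-transferases, 6.76e-05 for the respiratory chain and 0.000122 for ecdysteroid synthesis. In MAR-AB it was 0.000501 for carboxyl/cholinesterases, 9.88e-06 for ABC transporters, 0.0101 for ecdysteroid synthesis and 0.000122 for the nervous system. In Tomato-2h it was 0.0391 for P450s, 0.000741 for target sites and 0.00958 for the nervous system, and in Tomato-12h 0.0269 for ABC transporters and 0.000741 for target sites. In Tomato-5G it was 0.00204 for glutathione S-transferases, 0.000521 for ABC transporters and 0.0391 for the nervous system. On median-centred ratios camera gave 0.0145 for glutathione S-transferases in MR-VP and in Tomato-5G and 0.00614 in Tomato-2h, 0.0186 for the respiratory chain in MR-VP, 0.081 for carboxyl/cholinesterases in MR-VP, and 0.0379 for the respiratory chain in Tomato-2h with the direction reversed; the cause was not tested.

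Named genes were compared 2545 times with their main value: 2486 kept direction and side of the threshold, 56 lost the call, 2 gained it (TuCCE-41-AChE in MR-VP, from processed intensities and with offset 0) and 1 reversed. That one is an unnamed target in MAR-AB, at -4.42 as the mean of 3 probes and 1.68 with its brightest probe, since its probes ranged from -7.97 to 1.68. Dim signals limit the sizes of large falls, which are bounds where a group was not well above background.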

Other observations

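The tests of the CYP392 family were chosen after values of its members had been seen. P450 names on the array show which subfamilies moved. Of 44 tested CYP392 members, 19 were higher in MR-VP, against 0 of 42 members of other named P450 families (Fisher's exact test, 2-sided, adjusted over 4 groups, p = 1.36e-06), and 21 against 3 in MAR-AB (adjusted p = 5.26e-05). In Tomato-12h the counts were 6 against 5 (adjusted p = 1) and in Tomato-5G 10 against 4 (adjusted p = 0.192). Family members can share signal on similar probes and are not independent, so these p values may be too small. On tomato the share of CYP392 members that rose did not pass the test of a difference from other families. P450s with no family number in their name were left out, and some of these rose too. Of all 103 P450s, 25 were higher in MR-VP and 31 in MAR-AB, more than the test counted.

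Within CYP392, the D subfamily was higher in 9 of 11 members in MR-VP, 8 in MAR-AB, 4 in Tomato-12h and 7 in Tomato-5G, with none lower. Of 20 members of the A subfamily 6 were higher in MR-VP and 8 in MAR-AB, and in Tomato-5G 1 was higher and 5 were lower. Its medians were 0.602, 0.929 and 0.357 in the same order, and the difference between groups was not tested for the subfamily. Both measured CYP392B members were called in Tomato-12h and Tomato-5G, at medians of 2.13 and 4.60, and neither in a strain. CYP392E members were higher in 4 of 10 cases in MR-VP and in 5, with 1 lower, in MAR-AB, and in 0 on tomato. In the CYP385 family 4 of 10 members were higher in both Tomato-12h and Tomato-5G, 2 in MAR-AB and 0 in MR-VP. Among delta-class glutathione S-transferases 3 of 13 were higher in MR-VP and in Tomato-5G and 5 in MAR-AB, with 1 lower in each of the last 2.

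Of the 333 targets called in Tomato-12h, 88 were called the same way in Tomato-5G and 46 the opposite way. Tomato-2h and Tomato-12h, on 1 slide, had 30 targets called the same way. Some falls were to levels not well above background: in Tomato-5G 37 of 539 lower targets were dim on every group array, and for 24 of 397 higher ones London was. For MAR-AB these counts were 21 of 350 and 19 of 325.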
